A study of Mus musculus with 2 samples.

How the data were processed

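Single-cell RNA was measured from mouse bone marrow cells sorted as Lineage-negative, c-Kit-positive and Sca1-negative, a gate that holds the progenitors committed to the myeloid, erythroid and megakaryocyte lineages and is called LKS- in the sample titles. The sample labels give the 10x Genomics 3′ kit, version 3, the strain C57BL/6 and a genotype of Control or Runx1 KO. There was 1 Control library, made from the pooled marrow of 1 Runx1f/f and 1 Runx1f/- mouse per the labels, and 1 library labelled Runx1 KO, for which the number of mice is not given in the sources used here. Another label field describes the cells as coming from embryos; the tissue and extraction fields, which name hind limb marrow, were followed. The library called wild type in the cell annotation was taken to be Control.

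The deposited matrix holds counts: unique molecular identifiers (UMIs) per gene and cell, for 31053 genes and 14795 cells. Cell Ranger and the mm10 genome build are named in the submitters' processing notes; versions and settings are not given in the sources used here. The deposited cell annotation holds counts (UMIs and detected genes per cell), the fraction of mitochondrial UMIs, a size factor that is a ratio of each cell's UMIs to a constant, and 2 columns of other values, the library name and a cell class named by a gene. How the authors assigned the 18 classes, of which 1 is called Unannotated, is not given in the sources used here. The sum of the matrix equalled the annotated UMIs in all 14795 cells. No cell had fewer than 1000 detected genes, while the highest mitochondrial share was 76.1%, so a minimum on genes and no maximum on mitochondrial UMIs had been applied before deposition. Genes were matched by identifier to GENCODE M21 on GRCm38 for their locations, and 31011 of 31053 identifiers matched (99.9%). There were 35 symbols shared by more than 1 identifier, whose entries were kept apart.

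The following choices were made before the data were examined: the gene lists, the naming rule, the main class, the minimum and the pseudocount. UMIs were summed over the cells of a library, or over its cells of 1 class, and given as counts per 1000000 (CPM) of that sum. Log2 ratios are log2 of the CPM in the library labelled Runx1 KO over the CPM in Control, after adding a pseudocount of 10 to both. Genes counted as measured when they reached 30 CPM in the higher library and 100 UMIs over both. Classes were compared when each library held at least 200 of their cells, which left Car1, Pf4, Ly86, CD34, Gstm1/CD63 and Hba-a2. Gstm1/CD63 was the main class, as the largest in the neutrophil lineage, since the series title concerns neutrophils. With 1 library per group no test between genotypes, p-value or count of differing genes is given. Shares of cells carry exact (Clopper-Pearson) 95% intervals and ratios of summed UMIs exact Poisson 95% intervals; both cover counting error only and not the spread between mice. A share of 0 cells is given with the upper limit that 3 cells would set.

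Each list was summarised by the median log2 ratio of its measured members, by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, and by the members at least 1.5-fold higher or lower. Intervals of medians come from 1000 redraws of the counts. The 17 gene lists were Toll-like receptor (TLR) pathway components, NF-kB subunits and feedback targets, inflammatory cytokines and chemokines, interferon-stimulated genes, primary granule genes, secondary and tertiary granule genes, Runx family and myeloid transcription factors, ribosome biogenesis, endoplasmic reticulum stress, p53 targets, S phase, G2/M, immediate-early and heat-shock genes, MHC class II, mitochondrially encoded genes, sex-linked genes and cytosolic ribosomal proteins. The 14 cell type marker lists were multipotent progenitor, megakaryocyte, erythroid, neutrophil progenitor, monocyte progenitor, dendritic cell, basophil and mast cell, eosinophil, lymphoid progenitor, mature B and plasma cell, T, NK and innate lymphoid cell, mature neutrophil, macrophage, and stromal and endothelial cell. Genes were named by a fixed rule: by log2 ratio among measured genes, the 12 highest and 12 lowest in the main class, the 8 highest and 8 lowest in the whole library and the 4 highest and 4 lowest in each other compared class, the gene Runx1, and up to 4 members of each gene list with the largest absolute log2 ratio in the main class. Predicted or clone-named genes, sex-linked genes and mitochondrial genes were left out of that ranking. Any other gene was chosen after its values were seen, as stated beside it.

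Own clusters served as a check on the classes. Counts were scaled per cell and log-transformed, and Leiden clustering ran on the 2000 most variable genes, 30 principal components and 15 neighbours at resolution 0.5, with both libraries together and mitochondrial genes left out; each cluster was called by the marker list with the highest mean standardised expression, with "-like" added. Clustering was repeated without the genes that name the classes. Doublets were called per library with scrublet at an expected rate of 6%, which called 153 Control cells (2.22%) and 267 cells of the other library (3.38%); they were left in, and taken out as an alternative. For a comparison at equal depth, cells were thinned to 5000 UMIs and assigned to classes again by a vote of their 15 nearest neighbours, with 465 Control cells and 346 cells of the library labelled Runx1 KO left out for having fewer; 84.9% and 85.6% of the thinned cells kept their class.

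The other alternatives were edgeR TMM scaling, a median-of-ratios size factor, a pseudocount of 1 CPM, a minimum of 20 UMIs only, the mean over cells in place of the sum, cells under 10% mitochondrial UMIs only, equal class weights, and each cycle phase or matching own cluster alone. The split of the Control pool by sex was not run, because the cells of both libraries looked male: Xist had 10 UMIs in Control and 6 in the other library, and 85.6% and 88.4% of cells held a UMI from a Y-linked gene.

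The comparison was tested on simulated data, by drawing Poisson counts for both libraries from the pooled profile of the Gstm1/CD63 class, at their depths and over its 4145 measured genes, with known differences in some genes. Of 67 genes set to a 1.5-fold difference, 67 set to 2-fold and 66 set to 4-fold, 100% were recovered in the right direction, with median absolute errors of 0.03, 0.03 and 0.04 log2. Lists with no planted difference fell outside the central 95% of random lists in 6 of 100 draws, 20 genes raised 1.5-fold reached percentile 100, and 95.0% of the ratio intervals held the planted value. This checks the calculation under counting error only. The simulated counts held no spread between mice, difference in cell mix, free RNA or genes that vary together. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.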

Results

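The data describe 14795 single mouse bone marrow cells sorted for progenitors, 6906 from a Control library and 7889 from a library labelled Runx1 KO. Runx1 encodes a transcription factor that blood progenitors need to form platelets, lymphocytes and several myeloid cells. Each genotype had 1 library, and the Control library pooled marrow of 2 mice, 1 of which carried a germline Runx1 mutation on 1 allele, so the differences between the libraries could not be compared with a spread between animals, and all intervals below cover counting error only. Control held 162278272 UMIs with a median of 21593.5 per cell, and the library labelled Runx1 KO held 145590840 UMIs with a median of 16092. Median detected genes were 4464.5 and 3939 per cell. Cells with at least 10% mitochondrial UMIs made up 2.74% and 4.12%. Of 31053 genes, 20022 had at least 1 UMI. The series title places the study in the question of how Runx1 restrains cytokine production by neutrophils after Toll-like receptor (TLR) signalling, and the comparison asks which progenitors and which of their transcripts differ before neutrophils form.

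Runx1 transcripts were more abundant, not less, in the library labelled Runx1 KO. Runx1 (ENSMUSG00000022952, GRCm38 chromosome 16, 92601466 to 92826149, minus strand, protein coding) had 143 counts per 1000000 UMIs (CPM) in Control and 361 in the KO-labelled library, a ratio of 2.53 (95% interval 2.49 to 2.57). The direction was the same in all 6 compared classes. Runx1 had 253 and 668 CPM in the Pf4 class, 214 and 586 in the CD34 class, 116 and 310 in the Car1 class and 150 and 295 in the Ly86 class. In the Gstm1/CD63 class it had 78.8 and 239 CPM, a ratio of 3.04 (2.86 to 3.23), and in the Hba-a2 class 35.9 and 86.6. The labels do not say which part of the gene was deleted, and UMIs from its 3′ end do not check the deletion where the deleted part lies elsewhere.

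In the mix of progenitors, cells of the megakaryocyte lineage made up a far larger share of the KO-labelled library, basophil progenitors were almost missing from it, and the class of monocyte progenitors was smaller. Late neutrophil forms took a larger share, while the deposited neutrophil classes summed were alike in size. The Pf4 class, named by a chemokine gene of megakaryocytes, held 222 cells (3.21%, 95% interval 2.81 to 3.66) in Control and 1782 cells (22.6%, 21.7 to 23.5) in the KO-labelled library, 7.03 times the share. The Prss34 class, named by a basophil protease, held 337 cells (4.88%, 4.38 to 5.41) in Control and 1 cell (0.0127%, 0.000321 to 0.0706) in the KO-labelled library; the counting interval of the ratio of Control to KO-labelled ran from 68.6 to 15250.

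The Ly86 class, which carried monocyte markers, made up 19.2% (18.3 to 20.1) of Control cells and 7.01% (6.46 to 7.60) of KO-labelled cells, 2.74-fold less. The CD34 class of early progenitors made up 15.6% (14.7 to 16.5) and 8.61% (8.0 to 9.25). Of the 4 neutrophil classes, Gstm1/CD63 held 621 cells (8.99%, 8.33 to 9.69) and 657 cells (8.33%, 7.73 to 8.96), with overlapping intervals. Gstm1/Ly86, which shares its markers with monocyte progenitors, was smaller in the KO-labelled library, at 4.43% (3.96 to 4.94) and 1.74% (1.46 to 2.05). The later Fcnb class was larger, at 2.61% (2.24 to 3.01) and 4.03% (3.61 to 4.49), and so was Ltf, the class of the lactoferrin gene, at 0.724% (0.538 to 0.953) and 2.80% (2.45 to 3.19), 3.87 times the share. Cells of the Ltf class made up 94.4% of a mature neutrophil-like cluster of 54 Control and 233 KO-labelled cells. This class may thus hold mature cells rather than progenitors of the sorted gate, and its share is not read as progenitor output. Summed, the 4 neutrophil classes made up 16.8% (15.9 to 17.7) and 16.9% (16.1 to 17.7).

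The erythroid class Car1 made up 32.0% (30.9 to 33.1) of Control and 38.1% (37.0 to 39.1) of KO-labelled cells, and the later erythroid class Hba-a2 4.26% and 4.03%. Small lymphoid and dendritic classes held fewer KO-labelled cells: Cd74 held 56 cells in Control and 7 in the other library, Vpreb1 21 and 4, Ccl5 9 and 2, and Siglech 5 and 1. Fcrla held 6 Control cells and 0 of the 7889 KO-labelled cells, which allows a share of up to 0.0380%. The eosinophil class Prg2 held 37 and 25 cells, the macrophage class C1qb 7 and 6, and 143 and 175 cells were Unannotated.

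Clusters built again from the counts gave the same direction for the megakaryocyte, basophil and monocyte lineages, while the direction for the erythroid lineage depended on how the clusters were built and named. Megakaryocyte-like clusters held 7.63% of Control and 40.8% of KO-labelled cells, and the basophil and mast cell-like cluster 8.05% and 0.114%. Neutrophil-like clusters held 11.5% and 14.7%, so the neutrophil total was alike in the deposited classes only. Erythroid-like clusters held 32.1% and 28.8%, against 36.3% (35.1 to 37.4) and 42.1% (41.0 to 43.2) for Car1 and Hba-a2 together. With clustering that left out the class-naming genes, chosen after seeing the data, the difference for Car1 and Hba-a2 was 1.11 percentage points. There, a cluster of 425 Control and 12 KO-labelled cells, 67.7% of it Car1 class, was named basophil and mast cell-like. Another of 15 Control and 1239 KO-labelled cells, 67.5% of it Car1 class, was named megakaryocyte-like. The direction thus rests on how these clusters were named. In the first clustering 1174 KO-labelled cells of the Car1 class (39.1%) lay in megakaryocyte-like clusters, against 274 Control cells (12.4%). Several clusters came almost wholly from 1 library: 1 erythroid-like cluster held 1449 Control and 6 KO-labelled cells and another 10 and 1900, and 1 megakaryocyte-like cluster held 2 and 1891, so a cluster of that kind may be the library itself.

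**Figure D1:**
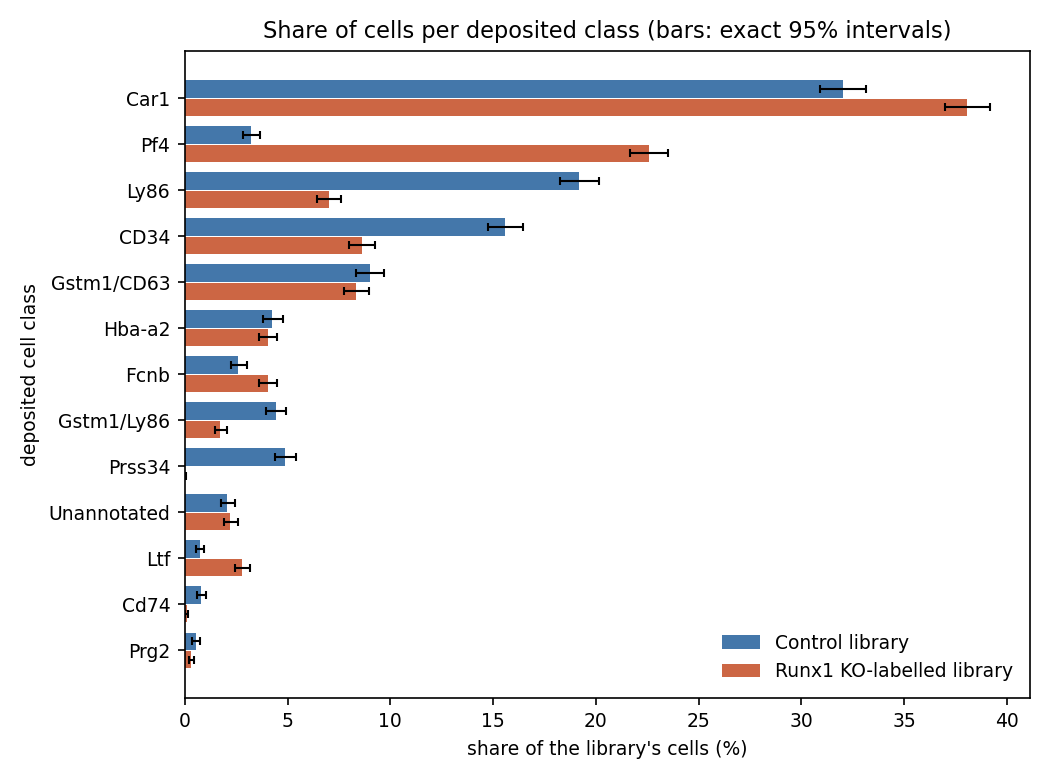
Share of each library's cells, in percent, in the larger classes of the deposited annotation, for Control and for the library labelled Runx1 KO, with exact 95% intervals that cover counting error only. The Pf4 class stands at 3.21% and 22.6% and the Ly86 class at 19.2% and 7.01%.

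Over all cells, platelet and late neutrophil transcripts were higher in the KO-labelled library, and basophil, monocyte and lymphoid transcripts lower. Treml1, a receptor stored in platelet granules (chromosome 17, 48359916 to 48367176), had 12.4 CPM in Control and 205 in the KO-labelled library, 16.6 times as much (15.8 to 17.3). Clec1b, a platelet-activating receptor (chromosome 6, 129397297 to 129409335), had 1.45 and 92.4 CPM, and Thbs1, thrombospondin (chromosome 2, 118111876 to 118127133), 1.47 and 69.4. The platelet integrin gene Itga2b (chromosome 11, 102453297 to 102470122) had 54.0 and 396 CPM, Nrgn 81.9 and 517, and Clca3a1 4.10 and 69.7. Of the neutrophil genes, Retnlg had 24.6 and 276 CPM and Chil3 38.2 and 236. All 9 measured megakaryocyte markers were at least 1.5-fold higher, with a median log2 ratio of 1.81, and 10 of 12 secondary and tertiary granule genes were, with a median of 1.57. The 3 measured mature neutrophil markers had a median of 0.89.

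Prss34 (chromosome 17, 25298394 to 25300165) had 148 CPM in Control and 0.110 in the KO-labelled library, 1344.2-fold less. Mcpt8, another basophil protease gene (chromosome 14, 56082166 to 56085273), had 142 and 5.95 CPM, and Csrp3 51.0 and 4.51. The basophil and mast cell list had a median log2 ratio of -1.41, with 4 of 7 members at least 1.5-fold lower. Ly6c2, a surface marker of monocytes (chromosome 15, 75108158 to 75111970), had 170 and 49.5 CPM. It was not confined to monocytes here, with 334 CPM in the Gstm1/CD63 class of Control. The monocyte progenitor list had a median of -0.85. Irf8, the transcription factor of monocytes and dendritic cells, had 156 and 52.1 CPM, and Satb1 37.3 and 10.4; both were chosen after their values were seen. Dntt, the DNA polymerase of early lymphocytes, had 35.2 and 1.22 CPM, and the lymphoid progenitor list a median of -1.21. Car1, a carbonic anhydrase of erythroid progenitors (chromosome 3, 14766216 to 14808368), had 865 and 147 CPM, Lgals1 657 and 161, and Ifitm1 317 and 68.1. The TLR list had a median of 0.04 and a mean of -0.24, and the multipotent progenitor list a median of -0.07 and a mean of 0.04.

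A few genes differed alike across the compared classes. The kinase gene Pim1 was higher in the KO-labelled library in all 6 classes, with log2 ratios from 1.07 in Hba-a2 to 1.88 in Pf4. Apoe was higher by 1.14 in Car1 to 1.98 in Ly86. The protease inhibitor gene Serpina3g, which missed the minimum in Hba-a2, was higher by 0.91 in Pf4 to 2.17 in Car1. Lgals1, which missed it in Pf4, was lower in the other 5, with log2 ratios from -2.81 in Car1 to -0.60 in Ly86. Platelet and neutrophil genes were among those higher in all 6 classes too. Itga2b was higher by 1.27 in Pf4 to 2.11 in Hba-a2 and Nrgn by 0.72 in Ly86 to 2.44 in Hba-a2. S100a8 was higher by 0.75 in Gstm1/CD63 to 3.52 in Ly86 and S100a9 by 0.93 in CD34 to 3.52 in Ly86. In Hba-a2, however, both differences all but vanished in the erythroid-like cells alone, and in Gstm1/CD63 both genes are read as background below. These values of S100a8 and S100a9 are thus not read as a shared difference in expression.

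Within the Gstm1/CD63 class, the largest in the neutrophil lineage, Ly6c2 and the basophil gene Mcpt8 were lower in the KO-labelled library. The megakaryocyte genes Pf4 and Itga2b, a survival kinase and an antiviral membrane gene were higher, while Serpine2, of the same megakaryocyte marker list, was lower. The late granule genes Wfdc21 and Lcn2 were higher, and the main enzymes of primary granules were little different or lower. The TLR pathway components that reached the minimum, Ikbkb, Irak1, Tab2 and Unc93b1, were nearly equal. The adaptor genes Myd88 and Tirap, below that minimum and chosen after their values were seen, were higher. The class itself was not of 1 kind: 513 Control and 451 KO-labelled cells lay in neutrophil progenitor-like clusters, 8 and 170 in a multipotent progenitor-like cluster, and 79 and 15 in a monocyte progenitor-like cluster. In the neutrophil progenitor-like cells alone Ly6c2 had a log2 ratio of -2.46, against -2.61 in the class. Unless stated otherwise, values below are for the whole class, so its different mix in the 2 libraries may contribute to them. Its naming gene Cd63 (chromosome 10, 128900989 to 128912822) also differed, at 737 and 383 CPM.

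Ly6c2 was the gene furthest below Control in this class, with 334 CPM in Control and 46.4 in the KO-labelled library, 7.19-fold less (ratio 0.139, 0.129 to 0.15). In the Ly86 class of monocyte progenitors its log2 ratio was -0.45, so the difference was larger in this neutrophil class. Lgals1, which encodes galectin-1 (chromosome 15, 78926725 to 78930465), had 578 and 235 CPM. The basophil protease gene Mcpt8 had 44.6 and 8.52 CPM, the choline dehydrogenase gene Chdh 45.8 and 7.02, Car1 34.4 and 8.46 and the protease inhibitor gene Serpine2 45.0 and 14.6. Selenom, Chst13, Ldhb, Bace1 and Nt5dc2 were lower by 1.94-fold to 2.90-fold.

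Prdx4, a peroxidase of the endoplasmic reticulum that takes part in protein folding (chromosome X, 155323918 to 155340754), had 10.6 CPM in Control and 75.9 in the KO-labelled library, 7.13 times as much (6.12 to 8.34). The kinase gene Pim1, a target of cytokine receptors, had 43.6 and 161 CPM, 3.68 times as much (3.40 to 3.99). Rhoj had 3.99 and 47.5 CPM, Serpina3g 20.8 and 111, and the transporter gene Spns1 17.2 and 69.9. Apoe, which encodes a lipid carrier, had 194 and 557 CPM, and F13a1, the coagulation factor XIII gene of monocytes and megakaryocytes, 18.9 and 73.4. Pf4 had 14.5 and 74.9 CPM and Itga2b 21.6 and 73.3. In the erythroid Car1 class of the same libraries Pf4 had 153 and 102 CPM, so Pf4 in the Gstm1/CD63 class stayed below its level there.

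**Figure D2:**
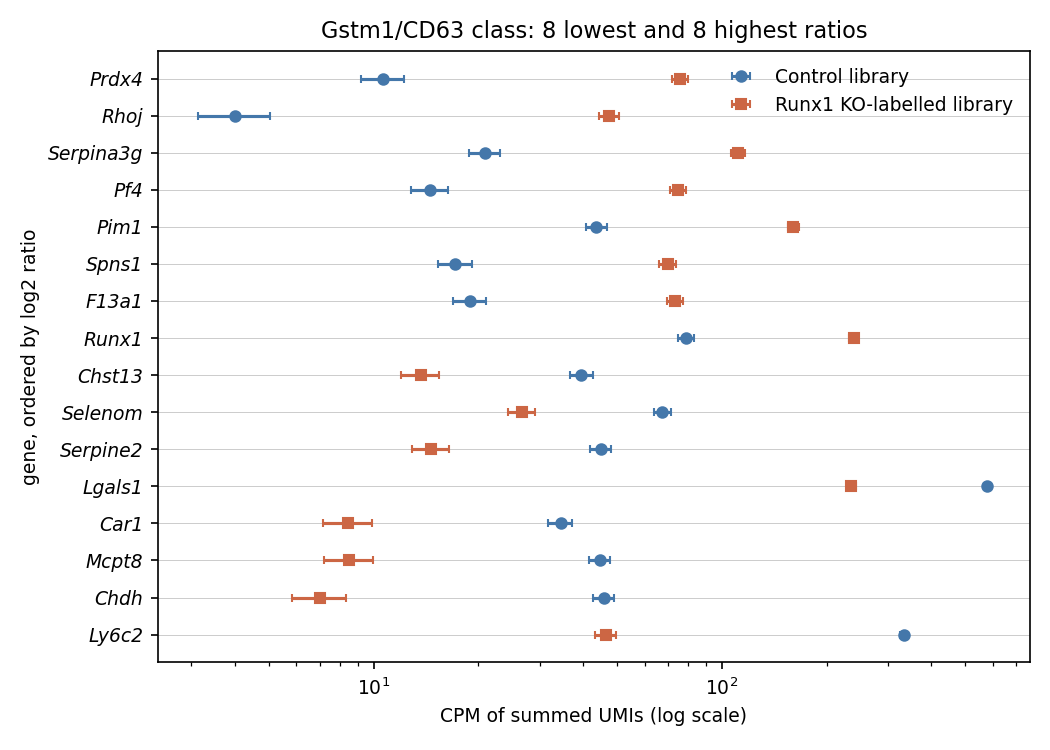
CPM on a log scale, in Control and in the library labelled Runx1 KO, of the 8 genes with the highest and the 8 with the lowest log2 ratio in the Gstm1/CD63 class, with exact Poisson 95% intervals. Ly6c2 lies at 334 and 46.4 CPM and Prdx4 at 10.6 and 75.9.

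Of the 30 TLR pathway components, 4 were measured in the Gstm1/CD63 class, and their median log2 ratio was 0.10 (percentile 83.8 of random lists); none differed by 1.5-fold. In S phase cells alone the median of the TLR pathway components was -0.025. The kinase gene Ikbkb had 51.3 and 61.5 CPM, and Irak1, the receptor-associated kinase, 77.0 and 77.5. Tab2 and Unc93b1 had log2 ratios of 0.13 and 0.07. The 4 NF-kB members had a median of 0.16 (percentile 94.7): Nfkb1 had a log2 ratio of 0.21, Nfkbib had 26.1 and 31.7 CPM and Sod2 146 and 160, while the feedback inhibitor gene Nfkbia was lower, at 44.1 and 31.1. Among cytokines, Tgfb1 had 225 and 301 CPM and Ccl9 129 and 116. The cytokine genes named in studies of neutrophil activation were near silent: Tnf had 15 UMIs in each library, Il1b 1 in each, and Il6 4 in Control and 2 in the KO-labelled library, too few to show a difference at this depth.

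The receptor side of the pathway lay below the minimum of 30 CPM, so the following genes were chosen after their values were seen. Cd14, the co-receptor for bacterial lipopolysaccharide (chromosome 18, 36725067 to 36726798), had 2.72 CPM in Control and 9.08 in the KO-labelled library, 3.34 times as much (2.41 to 4.70). Tlr4 (chromosome 4, 66827584 to 66930284) had 3.33 and 6.01 CPM, a ratio of 1.81 (1.31 to 2.52), and its partner Ly96 1.55 and 2.95. Tlr2 had 4.16 and 6.35 CPM, a ratio of 1.53 (1.13 to 2.07). The adaptor genes Myd88 and Tirap had ratios of 1.51 (1.29 to 1.77) and 1.80 (1.42 to 2.28), and Bcl3, an NF-kB cofactor, 2.86 (2.06 to 4.01). Cd180, a TLR4-like receptor, was higher at 1.94 and 7.52 CPM, whereas its partner Ly86 (chromosome 13, 37345208 to 37419036) was lower at 10.2 and 1.78.

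In the later Fcnb class, Cd14 had 4.62 and 11.4 CPM (ratio 2.48, 1.52 to 4.20) and Tlr4 4.62 and 8.11 (1.76, 1.05 to 3.04). In the Ly86 class Cd14 had a ratio of 3.09 (2.21 to 4.35) and Tlr4 of 3.56 (2.40 to 5.31). The intervals of Tlr4 included no difference in the Ltf class, at 1.27 (0.584 to 3.17), and in the CD34 class, at 0.953 (0.490 to 1.78). In the erythroid Car1 class, taken as background, Cd14 had 0.133 and 0.241 CPM and Tlr4 0.356 and 0.221, far below the myeloid classes. Cd180, Myd88 and Bcl3 were higher in the Car1 class too, at 6.52 and 22.8, 13.7 and 23.0, and 1.25 and 11.6 CPM, as were Tlr2, with a ratio of 1.52 (1.07 to 2.18), and Tirap, with 1.39 (1.17 to 1.65), so these 5 were not higher in myeloid cells alone. The gene Ly86 was also lower in the Car1 class, at 2.89 and 0.704 CPM (ratio 0.243, 0.163 to 0.356), and thus not in myeloid cells alone. Within the neutrophil progenitor-like cells of Gstm1/CD63 alone, Cd14 had a ratio of 2.96 (2.09 to 4.26) and Tlr4 of 1.76 (1.25 to 2.51).

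**Figure D3:**
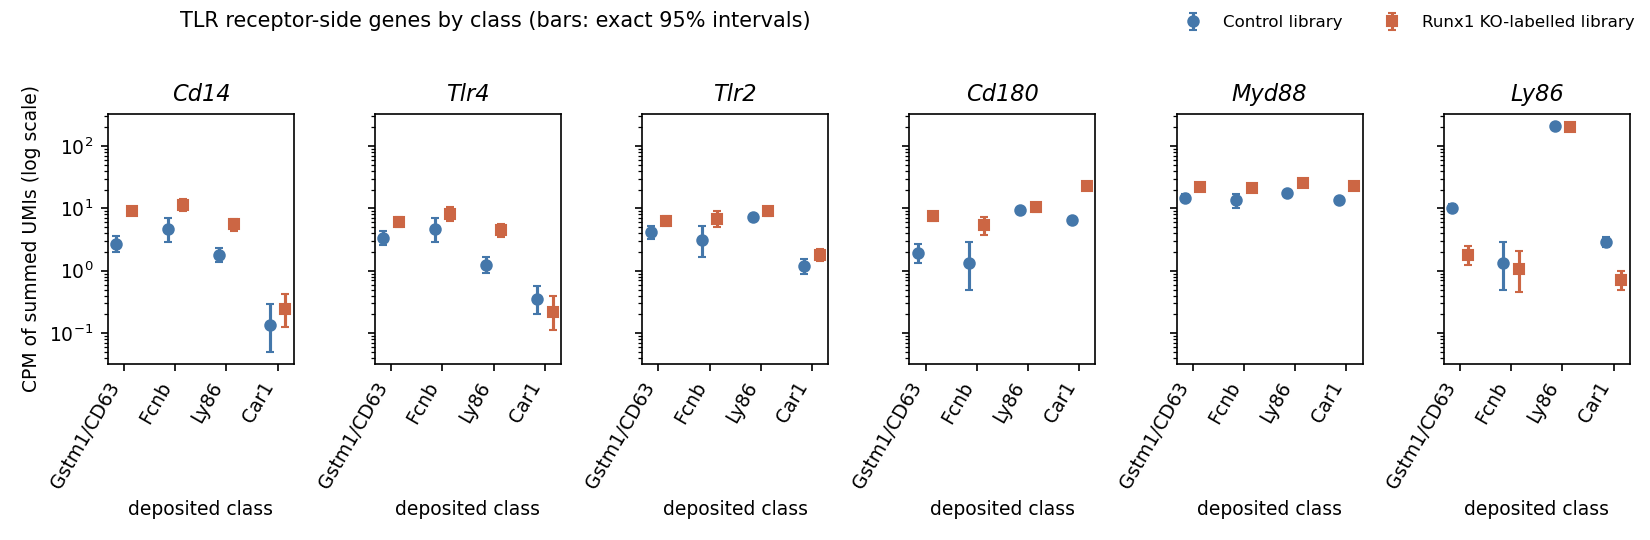
CPM on a log scale of Cd14, Tlr4, Tlr2, Cd180, Myd88 and Ly86 in 4 classes, in Control and in the library labelled Runx1 KO, with exact Poisson 95% intervals. In the Gstm1/CD63 class Cd14 lies at 2.72 and 9.08 CPM and Tlr4 at 3.33 and 6.01.

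Granule genes split by stage in the Gstm1/CD63 class. The 7 measured genes of secondary and tertiary granules had a median log2 ratio of 0.75 (0.64 to 0.87), above all random lists at percentile 100. That median is the value of S100a8, and without S100a8 and S100a9 the secondary and tertiary granule genes had a median of 0.39 over 5 members, an alternative chosen after seeing the data. Including the secondary and tertiary granule genes with as few as 20 UMIs gave 15 members and a median of 0.35. Wfdc21 had 20.1 CPM in Control and 60.6 in the KO-labelled library, and Lcn2, lipocalin 2, 16.6 and 44.3; both were far above their levels in the Car1 class, which reached 2.19 and 5.90 CPM in the KO-labelled library. S100a8 had 32.9 and 62.2 CPM and S100a9 11.7 and 32.9, but in the Car1 class they reached 52.6 and 66.7 in the KO-labelled library, so they are read as background here. Of 9 primary granule genes the median was -0.01; Prss57 had 234 and 124 CPM, the elastase gene Elane 7388.7 and 5800.7, and Serpinb1a 488 and 542.

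Interferon-stimulated genes were represented by 3 members with a median of 0.22, the value of Ifi47. Ifitm3 stood above it, at 130 and 326 CPM (ratio 2.5, 2.38 to 2.63), and Bst2 had 139 and 146. Among 14 Runx family and myeloid transcription factors the median was 0.06; besides Runx1, Zfpm1, the cofactor of GATA1, was higher at 17.9 and 32.6 CPM, and Runx2 at 24.2 and 35.2. G2/M genes had a median of 0.25 (percentile 100), led by Ube2c at 78.6 and 117 CPM, while S phase genes had -0.09. G2/M genes had a median of 0.50 when the class was limited to the neutrophil progenitor-like cells. Endoplasmic reticulum stress genes had a median of -0.12, with the chaperone gene Hspa5 at 1094.0 and 953 CPM, and Xbp1 was an exception at 121 and 193.

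The other gene lists lay close to 0 in the Gstm1/CD63 class. Ribosome biogenesis had a median of 0.09, MHC class II genes 0.16, immediate-early and heat-shock genes -0.04, and mitochondrially encoded genes -0.10. Cytosolic ribosomal proteins had a median of 0.04 and a mean of -0.01, and 0.00 with TMM scaling of the cytosolic ribosomal proteins. The p53 targets Bax and Aen had log2 ratios of 0.11 and 0.08, and the sex-linked genes Eif2s3y and Ddx3y 0.33 and 0.11. Of the marker lists, megakaryocyte had a median of 0.55, or 0.25 without called doublets, dendritic cell 0.23, multipotent progenitor 0.17, neutrophil progenitor -0.02 and erythroid -0.24. Monocyte progenitor markers had a median of 0.32 and a mean of -0.11, and basophil and mast cell markers a median of 0.25 and a mean of -0.33, as 1 member of each list was far lower. Eosinophil markers had 2 measured members, and lymphoid progenitor, mature B and plasma cell, T, NK and innate lymphoid cell and mature neutrophil markers 1 each, so no median is given; macrophage and stromal and endothelial markers had 0.

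In the Car1 class of erythroid progenitors, the KO-labelled cells carried more megakaryocyte and less erythroid transcript. Erythroid genes such as the master regulator Klf1 were lower, and early platelet genes were higher, although Pf4 itself was not. Genes for making ribosomes were slightly lower. Treml1 had 17.0 CPM in Control and 164 in the KO-labelled library, 9.65 times as much (8.96 to 10.4), Clca3a1 7.79 and 107, St3gal6 2.80 and 47.3, and Serpina3g 52.3 and 270 (ratio 5.16). Itga2b had 69.0 and 322 CPM, whereas Pf4 had 153 and 102; these were chosen after their values were seen, as were Klf1 and Car2. The interferon-inducible membrane gene Ifitm1 had 515 and 30.6 CPM, 16.8-fold less, Lgals1 423 and 51.6, and Csrp3 79.3 and 8.73. Ifitm1 and Csrp3 were also top genes of the basophil and mast cell-like cluster. That cluster held 84 Control and 2 KO-labelled cells of the Car1 class, so part of both differences may come from them.

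Of 8 measured megakaryocyte markers in the Car1 class, 6 were at least 1.5-fold higher, with a median log2 ratio of 1.35. The median of megakaryocyte markers was 1.26 in its erythroid-like cells alone. Erythroid-like clusters that came mostly from this class were each held by 1 library. They had 1449 Control and 6 KO-labelled cells, 287 and 18, and 10 and 1900, so the value of 1.26 does not compare like cells. Of 13 erythroid markers, 5 were lower and 1 higher, with a median of -0.54. Klf1 had 180 and 102 CPM, and Car2 1106 and 568. Primary granule genes had a median of -0.75, basophil and mast cell markers -0.95 and ribosome biogenesis -0.25. G2/M genes had a median of 0.26, but G2/M genes had -0.97 in the erythroid-like cells alone. That subset leaves out a megakaryocyte-like cluster of 71 Control and 1207 KO-labelled cells, 68.9% of them of the Car1 class, with the cycling genes Mki67 and Hmmr, chosen after their values were seen, among its top genes, so neither value is read as a difference in cycling. The naming gene Car1 had 2034.1 and 261 CPM, so the class may not have held the same cells in both libraries.

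In the Pf4 class of megakaryocyte progenitors, the platelet genes Clec1b, Thbs1 and Alox12 were higher in the KO-labelled library and Pf4 and Vwf lower. Genes for ribosome production and the cell cycle were lower. Clec1b had 36.6 CPM in Control and 438 in the KO-labelled library, 12.0 times as much (10.2 to 14.1), Thbs1 30.4 and 338, and the platelet lipoxygenase gene Alox12 3.66 and 102. Dlk1, which encodes a Notch ligand of fetal tissues, had 0.457 and 59.6 CPM, with 2 UMIs in Control and a ratio between 36.0 and 1076.9. C1galt1, a glycosyltransferase gene needed for platelet glycoproteins, had 187 and 26.9 CPM, the chromatin gene Hmgn3 90.4 and 17.0, the asparagine synthetase gene Asns 30.9 and 0.676, and Khdrbs3 30.7 and 0.915.

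Of 13 megakaryocyte markers in the Pf4 class, 7 were higher and 2 lower, with a median log2 ratio of 0.90. Marker lists of other lineages also had medians above 0, at 0.68 over 6 erythroid, 0.45 over 6 neutrophil progenitor and 1.24 over 3 mature neutrophil markers. Itga2b had 553 and 1347 CPM, Gp9 90.4 and 282, and Ppbp 16.0 and 144, while Pf4 had 5116 and 3469 and Vwf 174 and 98.9; these 5 genes were chosen after their values were seen. Ribosome biogenesis had a median of -0.46, S phase genes -0.30 and G2/M genes -0.33. Inflammatory cytokines and chemokines had a median of 1.08 over 3 members. The Control library supplied 222 cells of this class. A megakaryocyte-like cluster with Thbs1 and Clec1b among its top genes, 74.3% of it Pf4 class, held 2 Control and 1891 KO-labelled cells. Another, with Pf4 and Vwf among its top genes, held 454 and 122. The Pf4 class may thus not have held the same cells in both libraries.

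**Figure D4:**
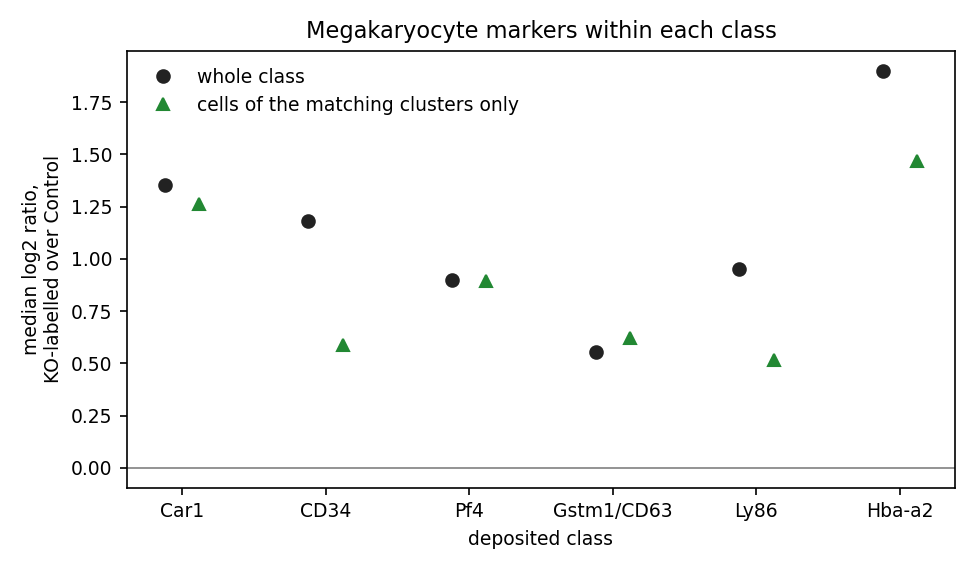
Median log2 ratio, KO-labelled library over Control, of the measured megakaryocyte markers in each of the 6 compared classes, for the whole class (circles) and for its cells in own clusters of the matching name (triangles). The megakaryocyte median of the Car1 class lies at 1.35 and 1.26 and that of the CD34 class at 1.18 and 0.59.

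In the Ly86 class of monocyte progenitors, the myeloid genes Chil3, S100a8, S100a9 and Retnlg were higher in the KO-labelled library. The interferon-stimulated genes Ifi27l2a and Ifitm3 were higher as well, and lymphoid transcripts were lower. Chil3, a chitinase-like gene of myeloid cells (chromosome 3, 106147554 to 106167564), had 1.73 CPM in Control and 228 in the KO-labelled library. The alarmin genes S100a8 (chromosome 3, 90668978 to 90670035) and S100a9 (chromosome 3, 90692632 to 90695721) had 7.41 and 190, and 7.90 and 195 CPM, and Retnlg 0.433 and 84.7. Dntt had 59.9 and 5.38 CPM, 11.1-fold less, Chdh 41.7 and 4.43, the survival gene Bcl2 181 and 62.5 (2.90-fold less), and the cyclin gene Ccnd2 142 and 51.2. Of the interferon-stimulated genes, Ifi27l2a had 18.0 and 116 CPM and Ifitm3 256 and 720, while Ifi47 had a log2 ratio of 0.31 and Bst2 of 0.017; all 4 were chosen after their values were seen, and their median was 0.88. Lymphoid progenitor markers had a median of -0.81.

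Part of this came from small groups of cells. The macrophage-like cluster, which was named by its marker score but also stood out by stromal genes such as Cxcl12 and Mgp, both chosen after their values were seen, held 5 Control and 45 KO-labelled cells of the Ly86 class. Mature neutrophil-like cells of the class numbered 0 and 7, neutrophil progenitor-like cells 13 and 28, and multipotent progenitor-like cells 205 and 29. Secondary and tertiary granule genes had a median log2 ratio of 2.18 in the whole Ly86 class and 0.88 without that cluster. Without it Chil3 had 0.650 and 9.77 CPM, Ifi27l2a 17.5 and 52.9 and Ifitm3 254 and 616, while S100a8 had 7.37 and 187 and Retnlg 0.433 and 88.9. In the monocyte progenitor-like cells alone, Dntt had a log2 ratio of -0.95, against -2.18 in the class, S100a8 2.35 and Retnlg 1.87.

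In the CD34 class of early progenitors, every measured megakaryocyte marker was higher in the KO-labelled library, and Serpinf1, Lsp1, Mcpt8 and Car1 were lower. Treml1 had 7.43 CPM in Control and 99.5 in the KO-labelled library, 13.4 times as much (11.4 to 15.9). Jam3, an adhesion gene, had 0.845 and 39.7 CPM, Clec1b 0.0889 and 37.9, with 2 UMIs in Control and a ratio between 117 and 3532.2, and Dlk1 0.534 and 107. Serpinf1 had 42.3 and 2.36 CPM, 17.9-fold less, the leukocyte gene Lsp1 49.9 and 7.69, Mcpt8 40.8 and 5.85, and Car1 34.5 and 2.71. Irf8, chosen after its values were seen, had 84.7 and 38.3 CPM. All 8 megakaryocyte markers were higher, with a median log2 ratio of 1.18. Monocyte progenitor markers had a median of 0.32, erythroid markers -0.05 and basophil and mast cell markers -0.13, each with members on both sides. Secondary and tertiary granule genes had a median of -0.15 and a mean of 0.15, and the median of the secondary and tertiary granule genes was 0.20 with a minimum of 20 UMIs.

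The class took its cells from different clusters in each library, with 19 Control and 143 KO-labelled cells in megakaryocyte-like clusters, 252 and 17 in the monocyte progenitor-like cluster, 110 and 5 in the basophil and mast cell-like cluster, 16 and 114 in neutrophil progenitor-like clusters and 607 and 318 in the multipotent progenitor-like cluster. Serpinf1 was a top gene of the monocyte progenitor-like cluster and Mcpt8 of the basophil and mast cell-like cluster. In the multipotent progenitor-like cells alone the megakaryocyte markers had a median of 0.59, Dlk1 a log2 ratio of 1.43, Treml1 of 1.23, Serpinf1 of -2.14 and Mcpt8 of -1.20.

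In the Hba-a2 class of later erythroid cells, globin transcripts were higher in the KO-labelled library and the erythroid enzyme gene Car1 was lower. The beta-globin gene Hbb-bs had 99.1 CPM in Control and 876 in the KO-labelled library, 8.84 times as much (8.35 to 9.37). Hba-a1 had 107 and 555 CPM, Hbb-bt 57.6 and 423, and the naming gene Hba-a2 28.1 and 192, all chosen after their values were seen. Car1 had 3413.6 and 716 CPM, Asns 208 and 38.0, Aldh1a7 33.8 and 5.05, and Bex4 169 and 67.8. Over 16 erythroid markers the median log2 ratio was 0.15, with 4 higher and 2 lower, and 3 megakaryocyte markers had a median of 1.90. Megakaryocyte-like clusters held 7 Control and 44 KO-labelled cells of the class, and the megakaryocyte median was 1.47 in the erythroid-like cells alone.

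Neutrophil transcripts were also higher in this class, but in few cells. Camp had 2.02 and 103 CPM, S100a9 33.1 and 366 and S100a8 28.0 and 308. In the erythroid-like cells alone the log2 ratios of Camp, S100a9 and S100a8 were 0.66, 0.03 and -0.062, and that of Hbb-bs was 2.40.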

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

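The marker sums given here were chosen after the other results were seen. Cells that the deposited annotation calls Unannotated, 143 in Control and 175 in the library labelled Runx1 KO, belong to no class compared above, and 4 marker lists summed over them were higher in the KO-labelled library by more than counting error. Megakaryocyte markers had 491 CPM in Control and 2930.1 in the KO-labelled library, 5.96 times as much (5.56 to 6.40). Mature neutrophil markers had 3.13 times as much (2.55 to 3.86). Stromal and endothelial markers, a small sum of 8.04 and 56.8 CPM, had 7.07 times as much (4.10 to 13.1). Erythroid markers had 433 and 607 CPM, 1.40 times as much (1.28 to 1.54).

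The same cells carried less of the lymphoid and monocyte programmes in the KO-labelled library. Lymphoid progenitor markers had 1975.3 CPM in Control and 51.6 in the KO-labelled library, 38.3-fold less, and mature B and plasma cell markers 394 and 11.6 CPM. Monocyte progenitor markers had 458 and 34.2 CPM, and dendritic cell markers 680 and 217. The Unannotated cells were thus of different kinds in the libraries, and no cause was tested. No named gene passed 1.5-fold in opposite directions in 2 compared classes by its log2 ratio, but some came close. Pf4 had -0.56 in the Pf4 class and 1.79 in Gstm1/CD63, and Ifitm3 -0.57 in Pf4 and 1.46 in Ly86. Ldhb had 0.51 in Ly86 and -0.98 in Gstm1/CD63.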

How the results depend on the processing

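Own clusters without the naming genes, the Ly86 class without its macrophage-like cluster, the granule list without S100a8 and S100a9, and the cells of matching own clusters alone were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because each genotype had 1 library, and for the same reason leaving out 1 library in turn was not possible. The split of the Control pool by sex was not run, as the cells of both libraries looked male. Scaling by TMM or by the median of ratios moved all log2 ratios of a comparison by between -0.052 and 0.039.

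For shares of cells, 17 of 30 comparisons with an alternative stayed within counting error, 12 moved and 1 reversed. The KO-labelled minus Control differences were 19.4 percentage points for Pf4, -4.87 for Prss34, -12.2 for Ly86, -6.97 for CD34, 5.84 for Car1 and Hba-a2 together, and 0.143 for the 4 neutrophil classes Gstm1/CD63, Gstm1/Ly86, Fcnb and Ltf. With own clusters at resolution 0.5 they were 33.2 for Pf4, -7.94 for Prss34, -17.9 for Ly86, -3.32 for Car1 and Hba-a2 together, which reversed, and 3.13 for the neutrophil classes. With own clusters without the naming genes they were 33.8 for Pf4, -12.8 for Prss34, -14.6 for Ly86, -10.8 for CD34, 1.11 for Car1 and Hba-a2 together and 4.19 for the neutrophil classes. After thinning to 5000 UMIs they were -13.6 for Ly86 and 1.49 for the neutrophil classes. In the clustering without the naming genes, 425 Control and 12 KO-labelled cells, mostly of the Car1 class, were counted as basophil and mast cell-like. That makes the value for Prss34 more negative and raises that for Car1 and Hba-a2. A cluster of 15 Control and 1239 KO-labelled cells, 67.5% of it Car1 class, was counted as megakaryocyte-like, which lowers the value for Car1 and Hba-a2. At resolution 0.5, 1174 KO-labelled and 274 Control cells of the Car1 class were counted as megakaryocyte-like. That takes from the value for Car1 and Hba-a2 there, so the reversal rests on how these cells were named. The cause of the moves was not tested.

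The log2 ratio of Runx1 over the whole library was 1.28, and 1.33 with a pseudocount of 1 CPM or 1.31 with equal class weights. In the Gstm1/CD63 class the median of the TLR pathway components was 0.10, and -0.025 in S phase cells or 0.23 in G2/M cells, and the median of the NF-kB subunits and feedback targets was 0.16, and 0.21 in G2/M cells. The median of the secondary and tertiary granule genes was 0.75; it was 0.90 with a pseudocount of 1 CPM, 0.35 with all 15 members of 20 or more UMIs, 0.39 without S100a8 and S100a9, 0.61 as a mean over cells, 0.94 in G1 cells and 0.61 in S phase cells. Members under the minimum have ratios that the pseudocount of 10 CPM pulls towards 0; the cause of the other moves was not tested.

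Over all lists, 441 of the alternative medians stayed within counting error, 205 moved, and of the medians of at least 1.5-fold 0 changed sign. Smaller medians did: the G2/M genes in the Car1 class went from 0.26 to -0.97 in the erythroid-like cells, the primary granule genes in Hba-a2 from 0.32 to -0.18 without called doublets, and those of the whole library from -0.15 to 0.14 with equal class weights. Of the named genes, 950 alternative values stayed within counting error and 401 moved, some of them near 0 across it. S100a8 in the Hba-a2 class reversed, from 3.06 to -0.062 in the erythroid-like cells alone; with called doublets left out S100a8 had 1.01. Depth limits the cytokine and receptor genes, many of which had under 30 CPM in each class.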

Other observations

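The tests of free RNA on megakaryocyte markers, of basophil cells in other classes, of doublets in the Hba-a2 class and of the Ly86 class without its macrophage-like cluster or with its monocyte progenitor-like cells alone were chosen only after the result was seen. The Fcnb class of later neutrophil progenitors, left out of the comparison because Control held 180 of its cells against 318, showed a mixed granule programme; its genes here were chosen after their values were seen. Ifitm3 had 62.5 CPM in Control and 245 in the library labelled Runx1 KO, the annexin gene Anxa1 270 and 578, Wfdc21 154 and 378, and the coagulation factor gene F13a1 20.2 and 102. S100a9 had 1019 and 438 CPM, the granule gene Ngp 65.2 and 11.3, Ly6c2 563 and 97.6 and Cd63 958 and 411. The eosinophil granule genes Prg2 and Prg3 were higher, at 12.1 and 80.2, and 13.2 and 35.0 CPM. The secondary and tertiary granule list had a median log2 ratio of -0.06 in this class.

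The macrophage-like own cluster held 14 Control and 54 KO-labelled cells, and its genes of largest fold over the other clusters were of mixed kind: Cxcl12, Mgp and Bgn of stroma beside Ctss and Trem2 of macrophages, so its name rests on the marker score alone; all genes of this paragraph were chosen after their values were seen. Fn1, fibronectin, had 2.49 CPM in Control and 57.1 in the KO-labelled library over the whole Ly86 class, and 2.25 and 17.5 without that cluster. Lyz2, lysozyme, had 236 and 1394 CPM with it and 225 and 419 without it.

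The megakaryocyte list had a median above 0 in all 6 compared classes, with 2 of 5 markers higher and 1 lower by 1.5-fold in Gstm1/CD63, but one of -0.37 over 3 markers in Fcnb. Free RNA gives all types a like level, so late neutrophils bound it, and the difference over the level in the lower of Fcnb and Ltf had a median of 3.97 in Car1, 4.40 in CD34 and 1.18 in Gstm1/CD63. Beyond counting error 5 of 7 markers passed 1 in Car1, 6 of 8 in CD34 and 2 of 4 in Gstm1/CD63, but against the higher of these classes 4, 4 and 0 did, and Cd9 and Rap1b, abundant in neutrophils, passed it in neither, so free RNA and expression cannot be told apart. Without called doublets the marker median kept at least 0.969 of its size in Car1 and CD34, which argues against doublets that scrublet can find there, while the megakaryocyte median went from 0.55 to 0.25 in Gstm1/CD63 and from 0.95 to 0.47 in Ly86. A megakaryocyte bias that starts in early and erythroid progenitors remains a candidate explanation, beside differences between the single libraries that no replicate can exclude.

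The basophil class Prss34 held 337 Control cells and 1 KO-labelled cell. Such cells under other class names were sought by Prss34 and Mcpt8, the named genes with the lowest log2 ratios over all cells. This finds only cells that still carried these transcripts, and cells of the lineage without them would be missed. Over all classes, 14 KO-labelled cells held 5 or more UMIs of Prss34 and Mcpt8, against 298 Control cells. Lower depth is argued against as the reason for so few cells with these transcripts. After thinning to 5000 UMIs, 62.5% of the Control cells of the class kept 2 or more of these UMIs. Of the KO-labelled cells, 13 of 7543 (0.172%) held as many. A shortage of basophil progenitors in the marrow that was sampled is a candidate explanation. Whether it goes with the genotype or with the mouse or sort was not tested, since there was 1 library of each.

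Secondary and tertiary granule genes were higher in the KO-labelled library in the Hba-a2 and Ly86 classes. They are out of place in Hba-a2, whereas in Ly86 at least Lyz2 was not foreign, with 236 CPM in Control. Free RNA would spread over cells by their depth. In Hba-a2, however, the 16 cells with the most granule UMIs held 91.7% of them, 9.02 times the share that depth gives. In Ly86 the top 28 cells held 5.50 times that share. There Lyz2 gave 20459 of the pooled UMIs, 5839 of them outside the macrophage-like cluster, against 2786 for S100a8 and 2857 for S100a9. The Ly86 value thus mostly follows Lyz2 in that cluster and cannot decide about free RNA for S100a8 and S100a9. Leaving out called doublets brought the Hba-a2 median to 0.197 of its value, so doublets with neutrophils may account for most of it. Leaving out the macrophage-like cluster brought the Ly86 median to 0.404 of its value, from 2.18 to 0.88, so that small group of cells may account for part of it. The remaining difference in Ly86 stays open. The class held 7 mature neutrophil-like and 28 neutrophil progenitor-like KO-labelled cells, against 0 and 13 in Control, which are 1 candidate. The secondary and tertiary granule genes still had 0.84 in the monocyte progenitor-like cells alone. Higher expression of them in these cells is another candidate, untested, and need not be a neutrophil programme.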
